A study of Mus musculus with 6 samples.

How the data were processed

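Rybp occupancy was measured by chromatin immunoprecipitation followed by hybridisation to promoter arrays (ChIP-chip) in mouse embryonic stem (ES) cells of 3 genotypes, wild type (WT), Eed knockout (Eed-KO) and Dnmt1 knockout (Dnmt1-KO). Rybp is a subunit of variant Polycomb repressive complex 1. Eed is a core subunit of Polycomb repressive complex 2, which methylates histone H3 at lysine 27, and Dnmt1 is the maintenance DNA methyltransferase. Per the labels, formaldehyde-fixed chromatin was precipitated with an anti-Rybp antibody, and precipitated (IP) and input DNA were amplified with T7 RNA polymerase, labelled with Cy5 and Cy3 and hybridised together. Cells were grown on irradiated feeder fibroblasts or on gelatin, without a statement of which culture had feeders. The promoter set consists of 2 array designs with different probes, so each genotype had 2 arrays and each promoter had 1 array per genotype. There were 6 arrays and no replicates, so no p-value was computed, and the number of arrays limits the precision.

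Per the file headers, the deposited spot values are background-subtracted and dye-normalised intensities from Agilent Feature Extraction, with spatial and multiplicative detrending and a linear dye factor per channel. The WT and Eed-KO files name version 9.5.3.1 and scanner model G2505B. The Dnmt1-KO files name version 10.1.1.1, another extraction protocol and scanner model G2505C, whereas the submitters' processing notes list version 9.5.3.1 for every sample. The authors' value table holds log10 ratios of Cy5 over Cy3. Against the scanner log ratios of the same array it differed by 1 constant per array, within 0.001 for at least 99.0% of probes on every array, which settles its scale and direction. How the constants were chosen is not stated. The medians of its columns on array 1 were -0.025 (WT), -0.0317 (Eed-KO) and -0.121 (Dnmt1-KO), and on array 2 -0.027, -0.0316 and -0.114.

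The level at each probe was log2 of the red over the green processed signal, that is IP over input, centred on the median of the array's non-control probes. Probes carrying a non-uniformity or population outlier flag on any of the 3 arrays of a design were left out, and saturated probes were kept. The probes are 45 to 60 bases long, with a median spacing of 182 bp. Coordinates, gene assignments and distances to annotated starts came from the annotation in the Dnmt1-KO files, which is later than that in the WT and Eed-KO files. The genome build is not given in the sources used here. Gene symbols were updated through RefSeq accessions with a GRCm38.p6 gene table used for names only, which matched 16943 of 17596 accessions, and other genes kept the symbol in the file.

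The level of a promoter was the mean over its window, the run of 6 neighbouring probes of the gene, spanning at most 3 kb, with the highest mean over the 3 genotypes. Genes with the same window count once. A promoter was called bound at a level of at least 1, that is 2-fold IP over input. Among promoters bound in WT or the knockout, a difference of at least 1 in size was called higher or lower. These are fixed rules of size. The background is the count of windows with the lowest mean and a level of -1 or less. Values carry the standard deviation (SD) over the 6 probes of the window, and differences the standard error (SE) over those probes, which covers probe scatter and no variation between cultures or hybridisations. For median differences at bound promoters, promoters were chosen on every other probe of the window and measured on the remaining 3 probes.

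The median of each of 12 gene lists was given its percentile among the medians of 10000 random lists of the same size, drawn with replacement. Random lists were matched on deciles of the level averaged over genotypes for differences and unmatched for WT levels. The lists, rules, thresholds and the 14 alternatives named next were fixed before the data were examined. The text names the 10 promoters with the highest WT level and the 3 highest members of each list. For each knockout it names, among promoters bound in WT or that knockout, the 8 lowest and 8 highest differences with all 6 probes in 1 direction, the 2 lowest and the highest bound member of each list, and Rybp, Eed and Dnmt1. Not every promoter chosen by this rule is named.

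The alternatives fixed beforehand were normexp background correction with an offset of 50, the authors' value table, centring on the mode, setting the arrays of a design to 1 median absolute deviation, bound levels of 1.5-fold and 3-fold, runs of 4 probes, all probes of a gene, filters on dim input probes, outlier spots and saturated probes, a lowess trend on probe GC content (span 0.3, 3 robust passes), and each array design alone. A further 4 were added after seeing the data: the scaling together with the GC trend, windows chosen on the WT and Eed-KO arrays, a GC trend taken as medians in 40 bins, and random lists matched on the level in the knockout that is not part of the difference. The binned trend departs from what had been fixed: it was run first by mistake and its results were seen, after which the lowess named beforehand replaced it. On simulated data with the real probe layout, all 132 genes given an enrichment above the bound level in simulated WT were called bound, as were 0 of 16105 promoters without one. The simulated WT arrays carried independent spot noise and no GC trend. On the real WT arrays log ratio and probe GC content correlated at r = 0.30 and 0.29, so the 0 does not cover calls due to GC content. With simulated differences of 1.5 between Eed-KO and WT, 100% of 44 lower and 100% of 44 higher genes were recovered. These genes were given an enrichment above the bound level and independent spot noise. A difference of 1.5 lies well past the rule of 1, so this recovery was close to assured. Smaller differences were not simulated. A GC trend added to the simulated Dnmt1-KO arrays alone called 8603 of these unenriched promoters bound, and 0 were called once the trend was removed. The trend was set at 1 log2 unit per SD of probe GC content and was not taken from the arrays. The 8603 therefore do not show how many calls GC content made on the real arrays. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, R 4.3.3 and limma 3.58.1.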

Results

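Rybp ChIP-chip profiles were collected from WT, Eed-KO and Dnmt1-KO mouse ES cells, with 2 arrays of different design per genotype and 237195 and 237185 non-control probes on the 2 designs. Windows of 6 probes were defined for 16327 promoters, with a median length of 1028 bp and a median distance of 476 bp between window centre and annotated start. In 251 windows the centre lay over 10 kb from the start. The WT and Eed-KO arrays had similar spreads of probe log ratios, with SDs between 0.41 and 0.47, whereas the Dnmt1-KO arrays had SDs of 0.96 and 0.91. Input signal was well above background at 99.9% of probes on the WT arrays and at 88.1% and 85.8% on the Dnmt1-KO arrays, for which the scanner software applied a stricter multiplier of 13 in place of 2.6. The median input signal above background was higher on the Dnmt1-KO arrays, at 104.5 and 101.6, than on the WT arrays, at 33.4 and 35.6. These values come from different scanners. Dnmt1-KO arrays were the only ones with saturated probes, 492 and 401. Scanner and extraction version differed in the same way, so genotype and scan batch cannot be told apart for Dnmt1-KO.

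**Figure D1:**
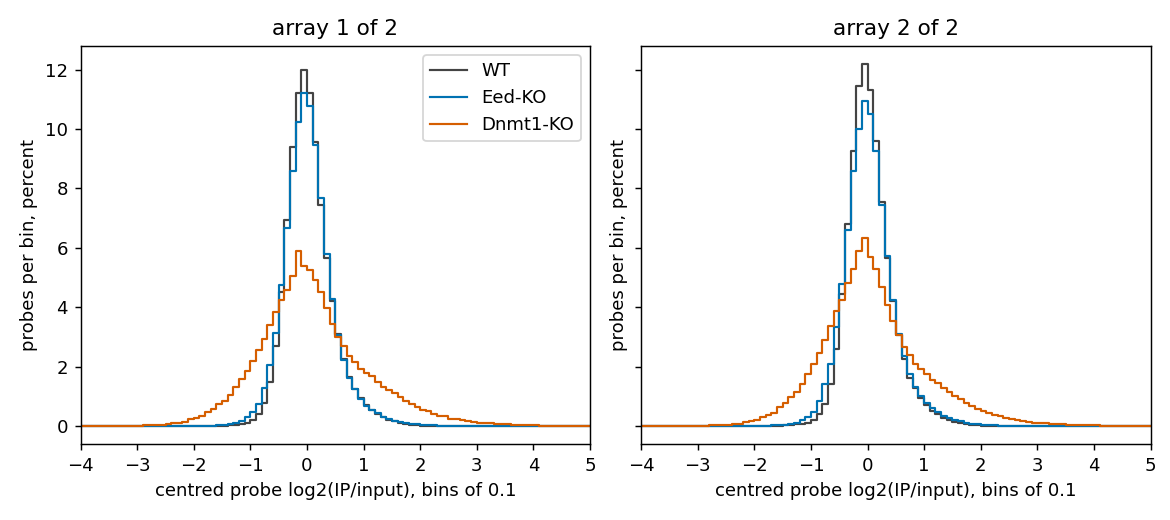
Distribution of centred probe log2(IP/input) on the arrays of the 2 designs, as percent of probes per bin of 0.1, for WT (grey), Eed-KO (blue) and Dnmt1-KO (orange). The Dnmt1-KO curves are wider on both sides, with 1st percentiles of -1.95 and -1.86 against -0.80 and -0.82 in WT.

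The promoters of the targeted genes were below the bound level in WT. Rybp had a level of 0.66 ± 0.18 (SD over 6 probes) in WT and 0.47 in Eed-KO, Eed had 0.52 ± 0.24 and 0.37, and Dnmt1 had 0.03 ± 0.25 and -0.05. In Dnmt1-KO the levels were 1.65, 1.89 and 0.91. Promoter probes outside a deletion do not check a knockout, so these values do not test the genotype labels.

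The WT arrays show where DNA precipitated with the anti-Rybp antibody was enriched over input in unmodified ES cells. The highest WT level was at Tdrkh, a gene of the piRNA pathway, at 2.63 ± 0.45, in a window on chromosome 3 from 94498154 to 94499062. Next came Zcwpw1, a reader of histone methylation in meiosis, at 2.57 ± 0.86 (chromosome 5, 138017462 to 138018323), and the testis-expressed helicase gene D1Pas1 at 2.23 ± 0.50 (chromosome 1, 188668459 to 188669397). The rest of the 10 highest were Fbxo46 at 2.14 ± 0.77, the germ-cell ADP/ATP carrier Slc25a31 at 2.11 ± 0.49, the meiotic cohesin gene Stag3 at 1.93 ± 1.04, the testis histone gene H2bc1 at 1.91 ± 0.36, A030009H04Rik at 1.90 ± 0.62, the T-box factor gene Eomes at 1.85 ± 0.50 and the deacetylase gene Hdac2 at 1.84 ± 0.99. In all, 841 of 16327 promoters (5.15%) were bound in WT, against 9 windows at -1 or less in the background count. Bound windows held a median of 3.63 CpG per 100 bases, against 2.58 over all windows. Log ratios rose with probe GC content on the WT arrays (r = 0.30 and 0.29), and 628 of the 841 stayed bound with that trend removed. The count depended on the bound level, with 3365 promoters at 1.5-fold and 45 at 3-fold, and on the processing, with 410 after normexp, 2554 with the arrays set to 1 spread and 16 over all probes of a gene.

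Developmental transcription factors had the highest list median in WT. Of 111 promoters, 75 were bound, with a median of 1.1. Their highest members were Eomes, Nkx2-2 at 1.6 ± 0.26 and Lhx8 at 1.56 ± 0.44. In the Hox clusters 15 of 32 were bound (median 1.00), led by Hoxa11 at 1.26 ± 0.42, Hoxb3 at 1.23 ± 0.31 and Hoxa10 at 1.21 ± 0.23. Among signalling and morphogen genes 19 of 49 were bound (median 0.91), led by the Notch ligand Dll4 at 1.62 ± 0.57, Igf2 at 1.53 ± 0.60 and Wnt1 at 1.50 ± 0.25. The WT medians of 9 of the 12 lists lay above the middle 95% of random lists, all but preimplantation genes, terminal differentiation genes and olfactory receptors.

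The germ-line and meiosis list was divided, with 26 of 83 promoters bound and a median of only 0.55 (quartiles 0.17 and 1.25), and its highest members Tdrkh, Slc25a31 and Stag3 were among the 10 highest of all. Imprinted genes had 11 of 35 bound (median 0.80), led by Dio3 at 1.65 ± 0.32, Igf2 and Grb10 at 1.43 ± 0.20. Pluripotency genes had 6 of 39 bound (median 0.68), with Tcl1 at 1.53 ± 0.29, Tfap2c at 1.28 ± 0.21 and Trim28 at 1.27 ± 0.54. Genes of Polycomb complexes had 6 of 45 bound (median 0.48), among them Mga at 1.71 ± 0.68 and Bcor at 1.22 ± 0.47. Markers of fibroblasts, the feeder cell type, had 6 of 36 bound (median 0.47), with Vim at 1.27 ± 0.30, Twist2 at 1.19 ± 0.33 and Fbn1 at 1.14 ± 0.28.

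Few or no promoters were bound in the remaining lists. Rpl3 at 1.12 ± 0.57 was the 1 bound promoter among 81 of housekeeping genes, whose median of 0.42 was still above the 0.27 of all promoters, and the window shared by Eno3 and Pfn1 was at 0.81. Gata2 at 1.07 ± 0.59 was the 1 bound promoter among 16 of preimplantation genes (median 0.25), above Arg2 at 0.87 and Slc34a2 at 0.86. None of 65 promoters of terminal differentiation genes was bound (median 0.03). Their highest were the window shared by Fgb and Plrg1 at 0.88, Myh6 at 0.68 and Lor at 0.55. The Myh6 window was centred 16057 bp from the annotated start. Of 783 olfactory receptor promoters 0 were bound (median -0.10), and the highest were Olfr94 at 0.91, Olfr279 at 0.56 and Olfr38 at 0.49.

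**Figure D2:**
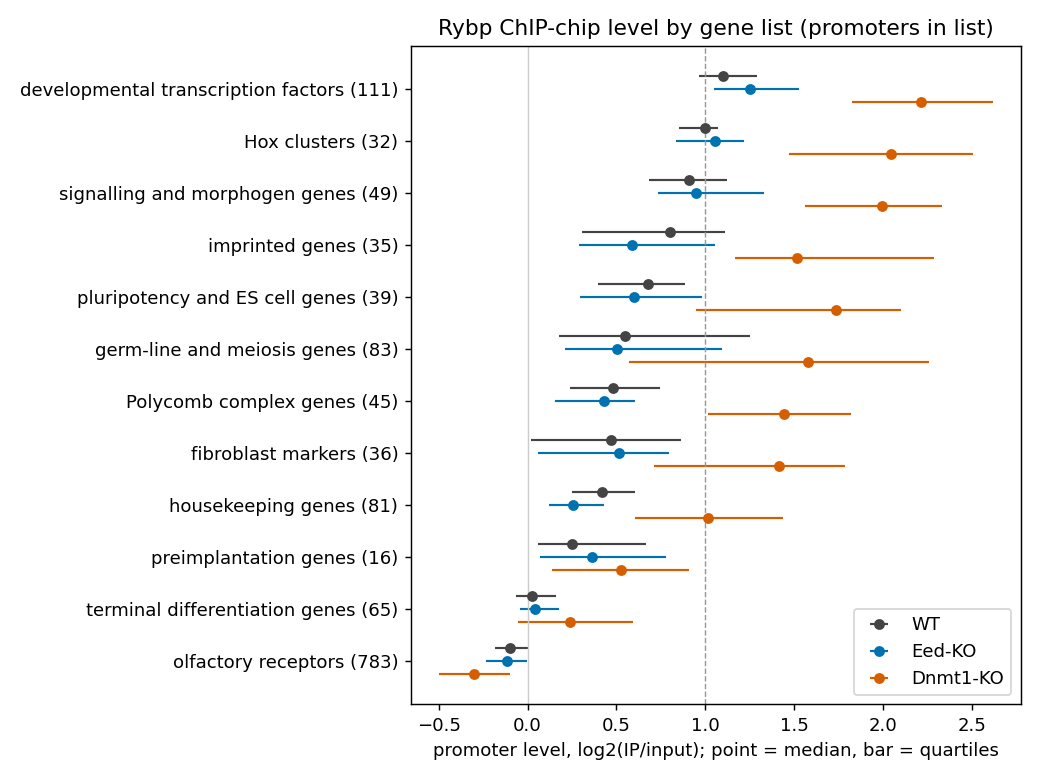
Median promoter level, log2(IP/input), of each gene list in WT (grey), Eed-KO (blue) and Dnmt1-KO (orange), with bars from the first to the third quartile over the promoters of the list, whose number stands in parentheses, and a dashed line at the bound level. The WT and Eed-KO medians were 1.1 and 1.25 for developmental transcription factors, 0.80 and 0.59 for imprinted genes and -0.10 and -0.12 for olfactory receptors.

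**Figure D3:**
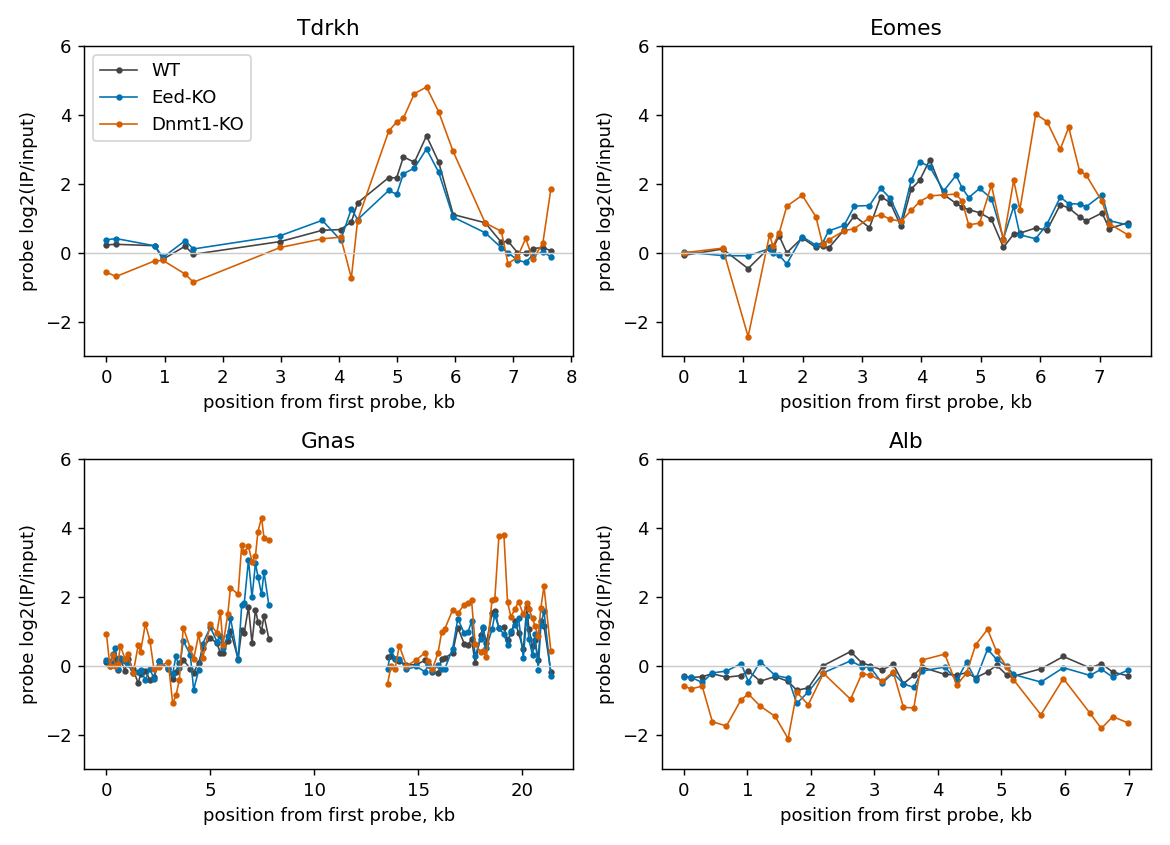
Probe log2(IP/input) against position from the first probe, in kb, at Tdrkh, Eomes, Gnas and Alb, chosen after their values were seen, for WT (grey), Eed-KO (blue) and Dnmt1-KO (orange), 1 point per probe, with lines broken over gaps of more than 3 kb. The window levels of Tdrkh were 2.63, 2.27 and 4.13, and no WT probe of Alb, a liver gene, reached the bound level.

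The comparison of Eed-KO with WT asks whether Rybp occupancy of promoters depends on Polycomb repressive complex 2. Rybp binding was largely retained without Eed. Of the 841 promoters bound in WT, 645 (76.7%) were also bound in Eed-KO, where 940 were bound in all against 27 background windows. A further 295 passed the bound level in Eed-KO only and 196 in WT only. Of the 111 promoters of developmental factors 88 were bound, against 75 in WT. With the arrays set to 1 spread these counts were 109 and 108, and the totals turned, with 2004 promoters bound in Eed-KO and 2554 in WT. By the rule of a 2-fold difference 0 promoters were lower in Eed-KO and 1 was higher, the imprinted gene Gnas. Its level was 2.57 ± 0.45 against 1.29 ± 0.40 in WT (chromosome 2, 173928712 to 173929503). At another annotated start of Gnas, Eed-KO probes lay on both sides of WT, at 1.05 against 1.52 (173940433) and 1.39 against 0.95 (173941710). A fall of 1 takes a promoter at the bound level to 0, and only 45 of the 841 reached 3-fold, so the rule could miss partial losses. By a difference of 0.5, 23 promoters were lower and 50 higher. The median difference at the 934 promoters chosen in WT was 0.02 (quartiles -0.16 and 0.19), and at the 1018 chosen in Eed-KO it was 0.10. With 1 spread 11 promoters were lower and 2 higher, and the median difference was -0.12.

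Among promoters bound in WT or Eed-KO with all 6 probes in 1 direction, the lowest differences were at Klhl9 (-0.93 ± 0.08 SE), D1Pas1 (-0.87 ± 0.13), Sfi1 (-0.77 ± 0.05), the imprinted gene Mkrn3 (-0.76 ± 0.22), Cntln (-0.74 ± 0.18), Mpp5 (-0.73 ± 0.25), Mfsd1 (-0.66 ± 0.07) and Trim68 (-0.66 ± 0.08). After Gnas (1.28 ± 0.05), the highest were the neurofilament gene Nefl (0.80 ± 0.13), the ES cell Ras gene Eras (0.72 ± 0.11), the neuronal factor gene Npas3 (0.71 ± 0.19), Cyp1b1 (0.71 ± 0.10), the homeobox gene Msx1 (0.71 ± 0.16), Zmiz1 (0.70 ± 0.41) and Adcy8 (0.69 ± 0.11). Nefl, Eras, Npas3 and Cyp1b1, among the highest, and Mpp5, among the lowest, lie in chromosomal segments whose input and IP signals were both higher in Eed-KO. Over these segments the median ratio differed by at most 0.04. That median is taken over all probes of a segment, so it cannot show whether the ratios at these windows were affected. The segments hold 5207 (chromosome X), 12825 (chromosome 12), 4517 (chromosome 14) and 2347 (chromosome 17) of 474380 probes. This is a far smaller share than that of their promoters among the 8 highest. Whether the segments contribute to these differences was not tested.

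The lists shifted by small amounts in opposite directions. Developmental transcription factors had a median difference of 0.20, with 93 of 111 promoters above 0, at the 100th percentile of level-matched random lists, and their bound members included Tbx15 (-0.20 ± 0.16) on the low side and Msx1 as the highest. Signalling genes had 0.13, with 41 of 49 above 0 (percentile 99.97), from Jag1 (-0.09 ± 0.10) and Dll1 (0.01 ± 0.10) to Wnt1 (0.49 ± 0.09). Housekeeping genes had -0.14, with 8 of 81 above 0, below all random lists, and Rpl3 was at -0.32 ± 0.09. The medians of these 3 lists were 0.14, 0.09 and -0.23 with 1 spread, and 0.10, 0.06 and -0.24 with the GC trend removed as well. With normexp they were 0.21, 0.10 and -0.08. The other 9 lists lay within the middle 95% of random lists before these steps, but when matched on the Dnmt1-KO level in place of the average the Hox clusters did not (percentile 98.3). Among them, the Hox clusters ranged from Hoxb3 (-0.32 ± 0.07) and Hoxa5 (-0.07 ± 0.08) to Hoxb9 (0.42 ± 0.05), and germ-line genes from Boll (-0.88 ± 0.56) and Nxt2 (-0.55 ± 0.15) to Lhx8 (0.63 ± 0.15). Polycomb genes ranged from Bmi1 (-0.29 ± 0.10) and E2f6 (-0.22 ± 0.05) to Rbbp7 (0.39 ± 0.07), and pluripotency genes from Trim28 (-0.18 ± 0.14) and Tcl1 (-0.13 ± 0.08) to Eras. Igf2r was at -0.18 ± 0.12, the fibroblast markers Fbn1, Ccn1 and Pdgfra at -0.19, -0.08 and 0.52, Gata2 at 0.00 and Olfr94 at 0.17.

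**Figure D4:**
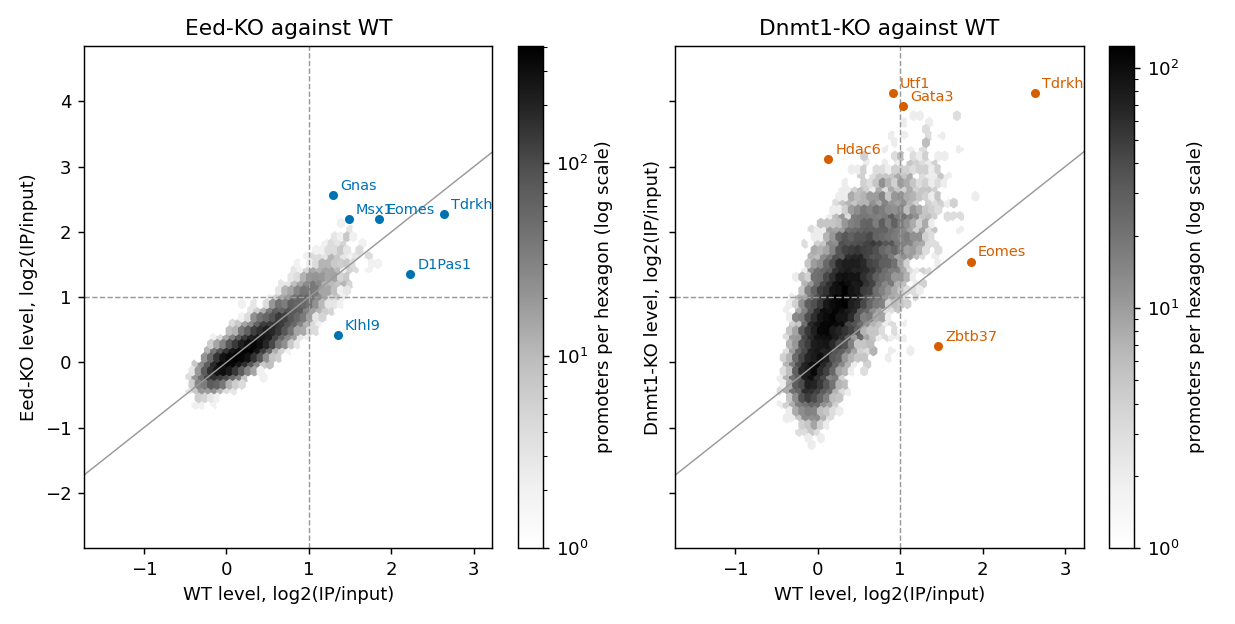
Promoter levels, log2(IP/input), in Eed-KO (left) and Dnmt1-KO (right) against WT, as hexagons shaded by number of promoters on a log scale, with the line of equality, dashed lines at the bound level and named promoters as points. Eed-KO levels follow the line (Pearson r = 0.90 across promoters, which are not independent replicates), while Dnmt1-KO levels lie mostly above it (r = 0.73).

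The comparison of Dnmt1-KO with WT asks whether Rybp occupancy depends on DNA methylation. Before scaling, many more promoters passed the bound level in Dnmt1-KO than in WT. This gap shrank with the arrays set to 1 spread and turned with the GC trend removed as well. Of the 841 promoters bound in WT, 816 (97%) were bound in Dnmt1-KO, where 7525 (46.1%) were bound in all, and with so many above a fixed level the overlap says little about stability. The background count was larger too, at 2385 windows of -1 or less. By the 2-fold rule 4070 promoters were higher and 2 lower, but with the arrays set to 1 spread 143 were higher and 112 lower. With windows chosen on the WT and Eed-KO arrays 2261 were higher and 4 lower. The median difference at WT-bound promoters was 1.02 (quartiles 0.57 and 1.45), 1.01 at promoters chosen in Dnmt1-KO, and -0.15 at WT-bound promoters after that scaling. Over all promoters the median difference was 0.61, or 0.07 after scaling and 0.33 with windows chosen on WT and Eed-KO. The direction of the Dnmt1-KO difference therefore rested on how the wider log ratios of these arrays were treated. At Tdrkh, for example, the difference was 1.49 and after scaling -1.24.

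Among promoters bound in WT or Dnmt1-KO with all 6 probes in 1 direction, the highest differences were at Utf1, a chromatin factor of ES cells, at 4.13 ± 0.56 against 0.91 ± 0.30 in WT (difference 3.22 ± 0.32 SE), the deacetylase gene Hdac6 (2.99 ± 0.62), Galnt17 (2.97 ± 0.63), Gata3 (2.90 ± 0.23), the hedgehog ligand Ihh (2.89 ± 0.37), the serotonin receptor gene Htr6 (2.89 ± 0.29), Pqlc3 (2.85 ± 0.36) and Osbpl6 (2.81 ± 0.65). These 8, picked as the highest, also lay above WT after scaling, between 0.67 at Ihh and 1.86 at Hdac6. The lowest were at Zbtb37 (-1.21 ± 0.26), Ppp1r10 (-1.04 ± 0.29), the ribosomal protein gene Rpl39 (-0.9999 ± 0.08, short of the rule), Lmln (-0.95 ± 0.25), Rbpjl (-0.77 ± 0.16), the homeobox gene Bsx (-0.74 ± 0.11), the protocadherin gene Pcdhga5 (-0.51 ± 0.06) and Sfi1 (-0.22 ± 0.06). After scaling Sfi1 was at -1.08.

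Against promoters of the same mean level and before scaling or GC removal, 4 lists lay outside the middle 95% of random lists, all on the low side. With the GC trend removed, housekeeping and preimplantation genes no longer did (percentiles 2.79 and 3.6) and the Hox clusters did (1.5), and with 1 spread preimplantation genes did not (6.54). On array 1 alone only 1 list did. The averaged level holds both sides of the difference, so lists high in WT tend to lie low in this match. Matched on the Eed-KO level, a choice made after the lists were seen, developmental factors (percentile 91.5) and housekeeping genes (2.56) lay within the middle 95%, and preimplantation genes (0.25), terminal differentiation genes (0.55) and olfactory receptors (0) below it. Developmental transcription factors were higher in Dnmt1-KO by a median of 1.08, where random lists gave 1.25, with 108 of 111 bound. Their bound members ranged from Eomes (-0.31 ± 0.22) and Isl1 (0.02 ± 0.36) to Gata3. The Eomes value holds for its window only. Outside it, probes at 870 and 1425 bp from the annotated start were at 4.02 and 3.64 in Dnmt1-KO, against 0.73 and 1.31 in WT. Housekeeping genes had a median of 0.51 (random lists 0.74), from Rpl3 (-0.94 ± 0.25) to Pkm (2.05 ± 0.54), and with windows chosen on WT and Eed-KO the median was -0.04. Preimplantation genes had 0.22 (random lists 0.52), with Slc34a2, Cbx2 and Lmx1a at 0.43, 1.30 and 1.48. Cbx2 is also in the Polycomb list and Lmx1a in the developmental list. Olfactory receptors had -0.20 (random lists -0.14), with Olfr94, Olfr38 and Olfr1349 at 0.60, 0.66 and 1.48.

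In the match on the averaged level the other 8 lists did not stand apart before these steps. The direction of most lists turned with scaling. After it the medians were -0.34 for developmental factors, -0.29 for the Hox clusters, -0.20 for signalling genes, -0.07 for germ-line genes, -0.10 for preimplantation genes, -0.07 for pluripotency genes, -0.01 for imprinted genes, -0.10 for housekeeping genes, -0.01 for terminal differentiation genes, 0.08 for Polycomb genes and 0.12 for fibroblast markers. The values before scaling follow. Of the germ-line and meiosis genes 49 of 83 were bound, with a median difference of 0.71 and bound members from Nxt2 (-0.57 ± 0.23) and Smc1b (0.36 ± 0.24) to Taf7l (2.48 ± 0.75). Imprinted genes had 0.96, from Grb10 (-0.18) and Mkrn3 (0.06) to Gnas (2.31). The Hox clusters had 1.03, with the low members Hoxb1 (-0.17) and Hoxb9 (0.26), and signalling genes 1.01, from Gdf6 (-0.46) and Fgf9 (-0.04) to Ihh. Pluripotency genes had 0.87, from Pou5f1 (0.28) and Fgf4 (0.47) to Utf1, and Polycomb genes 0.84, from Bmi1 (-0.03) and Cbx8 (-0.02) to E2f6 (1.74). Fibroblast markers had 0.75, from Prrx1 (0.21) and Fbn1 (0.42) to Col5a1 (2.63), and terminal differentiation genes 0.23 (-0.24 with windows chosen on WT and Eed-KO), with the Fgb and Plrg1 window, Fabp1 and Ppy at 0.17, 0.83 and 1.76.

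How far the differences of the 2 knockouts went together depended on the processing. Over the 7576 promoters bound in any genotype, the Eed-KO and Dnmt1-KO differences correlated at r = 0.12 with shared WT probes and at r = 0.06 with the WT probes split between the comparisons. The split value was 0.15 with normexp, 0.17 with scaling and GC removal together, and -0.0434 over all probes of a gene. Unchanged simulated groups compared with the same WT arrays gave r = 0.31. The covariance was 0.0096 unsplit, against 0.0050 in the simulation, and 0.0059 split, against 0.00026 with simulated probes split in the same way (r = 0.0082). Part of any excess may come from the shared WT arrays. Of the 500 promoters with the highest WT level, 339 were among the 500 highest of Eed-KO and 187 among those of Dnmt1-KO, where unrelated rankings would share about 15.3.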

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

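The tests on the tails of the Dnmt1-KO log ratios and on the IP signal of chromosome 12 were chosen after the results were seen.

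The input channel, which the report uses only inside the ratio, differed between the lines on parts of chromosomes. With the GC trend removed, the chromosome median of the Eed-KO minus WT input difference was 0.14 on chromosome 12 and 0.10 on chromosome X, each over 5 median absolute deviations from the autosomes, a rule that left out chromosome Y (204 probes) and mitochondrial DNA (47 probes). Whether probe GC content matters stays open, since the 0.14 was picked with that trend removed and the step moved no autosome by more than 0.01, while a shift of the input channel alone is excluded by the IP difference of 0.16. Of the 5 Mb bins of the chromosome 83.3% had a median above 0, between the bounds set for a local and a chromosome-wide difference, and the excess ran from 30 to 120 Mb. A difference in copy number between the cell lines is a candidate explanation, not tested by other means, and since IP and input differed alike the median ratio of the segment differed by only 0.02.

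More promoters passed the bound level in Dnmt1-KO than in WT. With scaling and GC removal together fewer did, and more were lower than higher. Log ratios were wider in both directions, with 1st percentiles at least 2.28 times as far from 0 as in WT, which a general stretch of the log ratios requires. Log ratio and probe GC content correlated at r = 0.45 and 0.44 on the Dnmt1-KO arrays, against 0.30 and 0.29 in WT. Each array is centred on its own median, so a broad gain or a stronger GC trend may widen both tails too. The tails therefore do not separate these. In the input channel, signal and probe GC content correlated at r = 0.71 and 0.72 on the Dnmt1-KO arrays. The values were 0.40 and 0.43 in WT and 0.45 and 0.43 in Eed-KO. Input is not precipitated with the antibody, so a gain of Rybp binding would leave it unchanged. These values argue against such a gain as the only difference of the Dnmt1-KO arrays. They do not show how much of the higher ratios GC content accounts for. With the GC trend removed and windows picked anew 2093 promoters were higher, against 4070, and the values do not settle what share GC content may account for. With the arrays set to 1 spread, which would also remove a true general gain, 143 were higher and somewhat fewer were lower. The median difference at WT-bound promoters was then -0.15, while windows chosen on WT and Eed-KO without this scaling gave 2261 higher. Scanner, extraction version and genotype cannot be told apart here, and an effect of Dnmt1 loss on Rybp stays open and cannot be tested on these arrays.

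In Eed-KO the developmental factor promoters lay above and the housekeeping promoters below WT, with a gap of 0.34 between the list medians. The gap was 0.32 with the GC trend removed and 0.37 with the arrays set to 1 spread, so neither trend accounts for it. Level-matched random lists had medians of 0.03 (developmental) and -0.05 (housekeeping). That is a smaller gap in the same direction, so level may account for part of it. The gap was 0.27 on array 1 and 0.38 on array 2, which were separate hybridisations with different promoters and no replicates. Variation between chromatin preparations was not measured with 1 array per genotype and design. A dependence of Rybp on Eed that differs between these classes is a hypothesis only.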

How the results depend on the processing

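No paired analysis was possible because each group holds 1 array and no result comes from a test across samples. Counts were taken as the same within 1.5 times, and median differences and the split correlation within the SD between the 2 array designs. List medians were taken as the same within the standard error estimated from the quartiles of the list. The authors' value table, keeping outlier spots and leaving out saturated probes left each result the same. Centring on the mode left the counts, median differences and correlation the same and moved 21 list medians. Over all alternatives 343 list medians stayed the same, of which 36 each under the 1.5-fold and 3-fold bound levels cannot change, 259 moved and 10 reversed, where reversals of differences were counted only for lists outside the middle 95% of random lists. The cause of the changes below was not tested, except that stricter or looser bound levels and averaging over all probes change counts by construction. The alternatives fixed beforehand come first and those chosen after seeing the data last.

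With normexp, 410 promoters were bound in WT and 578 in Eed-KO, 1 was lower in Eed-KO, the Dnmt1-KO median difference was 1.24 and the split correlation of the 2 comparisons 0.15. With the arrays set to 1 spread, 2554, 2004 and 3240 promoters were bound in WT, Eed-KO and Dnmt1-KO. Then 11 were lower and 2 higher in Eed-KO, 112 lower and 143 higher in Dnmt1-KO, and the median differences at WT-bound promoters were -0.12 (Eed-KO) and -0.15 (Dnmt1-KO, reversed). List medians of Dnmt1-KO minus WT reversed for developmental transcription factors (-0.34), preimplantation genes (-0.10) and housekeeping genes (-0.10), and the sign also turned for the Hox clusters (-0.29), signalling (-0.20), germ-line (-0.07), pluripotency (-0.07), imprinted (-0.01) and terminal differentiation genes (-0.01). At 1.5-fold, 3365 and 3051 promoters were bound in WT and Eed-KO, 2 were higher in Eed-KO, and the median differences were -0.0330 and 0.92. At 3-fold, 45, 115 and 3386 were bound in the 3 genotypes, 0 were lower in Dnmt1-KO, and the median differences were -0.0484 and 1.12. Runs of 4 probes gave 1 lower and 2 higher promoters in Eed-KO, 4 lower in Dnmt1-KO, and 5 lists outside the middle 95% of random lists in Eed-KO.

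With all probes of a gene, 16, 43 and 503 promoters were bound, 0 were higher in Eed-KO, 0 were lower and 62 higher in Dnmt1-KO, the median differences were 0.12 and 0.71, 6 lists lay outside the middle 95% in Eed-KO, the split correlation was -0.0434, and the WT median of terminal differentiation genes was -0.0772. Without dim input probes, 1 promoter was lower in Dnmt1-KO and the WT median of terminal differentiation genes was -0.0041. Removing the GC trend gave 4941 bound and 2093 higher promoters and a median difference of 0.67 in Dnmt1-KO. Signal over background limits the ratios at dim probes. Of the 841 promoters bound in WT, 730 were kept without dim input probes, 628 with the GC trend removed and 352 with normexp. On array 1 alone 1 list lay outside the middle 95% in Dnmt1-KO.

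Scaling together with GC removal gave 2057, 1629 and 1783 bound promoters, 10 lower in Eed-KO, and 138 lower and 87 higher in Dnmt1-KO. The median differences were -0.11 and -0.31, the split correlation 0.17, the WT median of olfactory receptors 0.0399, and the Dnmt1-KO list medians -0.44 (developmental), -0.18 (preimplantation) and -0.23 (housekeeping), with the Hox clusters at -0.31, signalling at -0.26, germ-line at -0.12, pluripotency at -0.05 and imprinted genes at -0.07. Windows chosen on WT and Eed-KO gave 1 lower promoter in Eed-KO, 4 lower and 2261 higher in Dnmt1-KO, a median difference of 0.76 there, a split correlation of 0.0110 and a housekeeping median of -0.0383 and a terminal differentiation median of -0.24 in Dnmt1-KO minus WT. Matching random lists on the other knockout put 4 lists outside the middle 95% in Eed-KO and 3 in Dnmt1-KO, and not the same lists. The GC trend as bin medians gave 5006 bound and 2155 higher promoters and a median difference of 0.69 in Dnmt1-KO.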

Other observations

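The following gene families and segments were chosen after seeing the data, and all values are descriptions of these arrays. Among 193 gene families with a shared symbol stem and at least 10 promoters, the clustered protocadherins, cell adhesion genes of neurons, lay outside the middle 95% of random lists in both knockouts. In Eed-KO all 10 Pcdha promoters, 20 of 22 Pcdhb and 19 of 22 Pcdhg promoters were above WT, with median differences of 0.37, 0.24 and 0.23, each above the medians of 2000 level-matched random lists. In Dnmt1-KO, where the median promoter was 0.61 above WT, the medians were 0.04, -0.08 and 0.21, each below all random lists, though a match on the averaged level favours low values for families high in WT. With the arrays set to 1 spread the Eed-KO medians were 0.40, 0.17 and 0.13 and those of Dnmt1-KO -0.69, -0.48 and -0.52. The protocadherin genes are neighbours in a cluster, so their promoters are not independent. The pattern was not particular to them. In the Nkx family of homeobox genes, 11 of 12 promoters were above WT in Eed-KO, with a median of 0.25 (percentile 99.85). In Dnmt1-KO the Nkx median of 0.73 was at percentile 0.45. With the arrays set to 1 spread these medians were 0.19 and -0.43. Ribosomal protein genes went the other way in Eed-KO, with 3 of 47 Rpl and 8 of 42 Rps promoters above WT and medians of -0.17 for both. With the arrays set to 1 spread these medians were -0.32 (Rpl) and -0.26 (Rps). They also lay low in Dnmt1-KO, with medians of 0.14 (Rpl) and 0.45 (Rps) at percentiles 0 and 0.1, and -0.34 and -0.26 with the arrays set to 1 spread. Of the 193 families 30 lay outside the middle 95% of random lists in Eed-KO and 23 in Dnmt1-KO.

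The input signal fell into segments that separate the 3 lines. Relative to WT, input was higher in Eed-KO by 0.71 on chromosome 14 from 60 to 90 Mb and by 0.63 on chromosome 17 from 70 to 85 Mb, and lower on chromosome 14 from 95 to 125 Mb, at -0.41. Dnmt1-KO differed from WT at the same places by 0.67, 0.53 and -0.46, and from Eed-KO by -0.01, -0.03 and -0.10. On chromosome 12 from 30 to 120 Mb and on chromosome X from 5 to 50 Mb the Eed-KO input was above WT by 0.18 and 0.33, and that of Dnmt1-KO differed from WT by -0.03 and 0.0023. The IP signal differed from WT by amounts close to the input in each segment in Eed-KO, so the median ratio there differed by between -0.01 and 0.04. With few probes, Eed-KO minus WT was 0.17 in input and 0.13 in IP on chromosome Y (204 probes), and 0.34 in input but -0.58 in IP on mitochondrial DNA (47 probes), with the GC trend removed.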
